A study of Mus musculus with 12 samples.

How the data were processed

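RNA of single lung cells was measured in 12 samples: sorted mesenchymal cells in 4 libraries (2 PBS, 2 HDM, each from 3 pooled mice) and immune cells of 8 mice (4 PBS, 4 HDM). Per the labels' protocols, mesenchymal libraries were made with a 5' gene expression kit and immune libraries with a 3' multiplexing kit. The values are raw UMI counts per gene and barcode, as deposited by the authors, who per the labels ran Cell Ranger 3.1.0 with STAR on mm10, while per the file headers the mesenchymal matrices were written by Cell Ranger 7.0.0 and the immune ones by 7.0.1. Barcodes without cells had been taken out before, and the smallest total is 500 UMI. The immune matrices hold 32285 genes and 12 multiplexing tags, and the tags were used only to check the captures.

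Depth before filtering was 6365414 and 9680033 UMI in the mesenchymal PBS libraries and 10628811 and 20088508 in HDM, 8320617, 11824680, 20253664 and 4323438 in immune PBS mice and 9464675, 12620215, 9146212 and 10012084 in immune HDM mice. Barcodes with fewer than 200 genes, over 10% mitochondrial UMI or a doublet call by Scrublet were removed, at an expected rate of 0.8% for every 1000 barcodes. Cells of each compartment were clustered separately (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15): scaling to 10000 counts per cell, logarithm, 2000 variable genes, 30 components, 15 neighbours and resolution 1, with no alignment of libraries. A cluster was named by the cell type of which it held at least 3 markers, in at least 10% of its cells and 2-fold above the other clusters (10 CPM added), and was left unnamed otherwise, where markers of another type led among its 20 top genes, or where its 10 top genes held more markers of another type.

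UMI counts were summed per library and class, and a class was tested where each library had at least 20 cells. In cDC2 and neutrophils PBS mouse 4 fell short and was left out. edgeR 4.0.16 (R 4.3.3) compared HDM with PBS in each class by its quasi-likelihood test, with TMM scaling and its default expression filter, and Benjamini-Hochberg adjustment over the genes of the class at 0.05. The differences between classes were tested as the interaction of class and treatment, with the library as a block. Values are log2 fold changes with SE, and CPM as mean ± SD. A fold against a group with 0 counts is a lower bound set at 3 counts over the group. Mesenchymal and immune samples never entered the same fit, since kit and pooling differ.

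Genes are named by a rule: up to 4 per direction and class with the largest change among those with an adjusted p below 0.05, a mean of at least 50 CPM and groups that do not overlap, without immunoglobulin and T cell receptor segments, mitochondrial, ribosomal and unnamed genes. To these come up to 4 members of each list with the smallest p, and 2 panels of genes known from allergic lung inflammation. Lists with at least 5 tested members were tested by fry (limma 3.58.1), adjusted over the lists of a class, and counted also with the adjustment over the list alone. Fry asks whether members move on balance in 1 direction, its mixed test whether they change in either direction, and neither compares them with other genes. Camera with an estimated correlation was the alternative. Class shares were compared by exact permutation of libraries. Gene locations were matched by gene ID in GENCODE vM21 (178 of 178).

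Classes, markers, lists, panels, tests, thresholds and alternatives were chosen before the data were examined. The minimum of 10 cells for interstitial macrophages and their interaction, and clustering without called genes, were added afterwards. The alternatives were DESeq2 1.42.0 size factors and its Wald test, no expression filter, the replicate number as a block, leaving out each library, keeping doublets, a mitochondrial limit of 5% and resolution 2. The test was tested on simulated data with 200 changed genes: of 2-fold changes it recovered 60.5% in alveolar fibroblasts, 21.5% in smooth muscle, 84.0% in B cells, 42.5% in cDC2, 71.5% in classical monocytes and 50.0% in interstitial macrophages. Of 4-fold changes it recovered 79.5% (smooth muscle) to 97.0%, and at most 6.20% of calls were false. In the interactions it recovered 11.5% and 20.5% of 2-fold and 71.0% and 76.0% of 4-fold changes. Unnamed clusters and classes with too few cells were left out of the gene tests.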

Results

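Single-cell RNA libraries were made from the lungs of C57BL/6 mice, 6 to 8 weeks old, that had inhaled house dust mite extract (HDM) or saline (PBS). Mice received 25 µg of HDM or PBS into the nose on days 1, 8, 15, 16 and 17, and lungs were taken on day 18. Sorted mesenchymal cells gave 2 HDM and 2 PBS libraries, each of 3 pooled mice. Immune cells were tagged by mouse, 4 HDM and 4 PBS.

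Of 41452 cell barcodes, 39513 were kept, 29037 of them in the mesenchymal libraries and 10476 in the immune ones. A predicted doublet score removed 1757 barcodes, a mitochondrial share over the limit 181, and fewer than 200 genes 20. The mesenchymal PBS libraries kept 3093 and 5339 cells and the HDM libraries 7580 and 13025, with medians of 1667 and 1483 molecules (UMI) per cell in PBS and 1064 and 1060 in HDM. Immune mice had medians of 5618 to 6835 UMI per cell. Clusters were named by markers of known lung cell types. In the mesenchymal libraries, each HDM library held more doublets, 3.39% and 8.87% of barcodes, than the PBS libraries, 0.226% and 1.40%, while immune HDM mice held 0.503 to 0.629% and PBS mice 1.10 to 2.52%.

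Markers of other cells and of RNA handling also moved with the group over whole libraries. Ptprc, the common leukocyte antigen, was at 157 ± 16.3 counts scaled to a common library total (CPM) in the mesenchymal HDM libraries and 48.5 ± 2.02 in PBS (mean ± SD, n = 2 and 2), and the immunoglobulin light chain Igkc at 142 ± 2.61 and 20.4 ± 0.308. Hspa1a, a heat shock gene induced by tissue dissociation, was at 2389 ± 183 CPM in HDM and 5580 ± 496 in PBS, and the mitochondrial share at 1.87 ± 0.0443% and 2.45 ± 0.0633%. In immune mice the ribosomal protein share of all counts was 18.7 ± 0.275% in HDM and 13.7 ± 1.38% in PBS (n = 4 and 4), against 11.1 ± 0.133% and 10.9 ± 0.436% in the mesenchymal libraries. The macrophage genes Chil3 and Lyz2 went the other way in the immune mice, at 1442 ± 780 and 1813 ± 178 CPM in HDM and 5809 ± 605 and 4166 ± 363 in PBS.

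Adventitial fibroblasts and pericytes made up a smaller part of the mesenchymal libraries after HDM, and leukocytes a larger part. Adventitial fibroblasts were 4.04 ± 0.363% of kept cells in HDM and 11.7 ± 0.321% in PBS, pericytes 7.93 ± 0.781% and 15.9 ± 1.17%, and immune cells 16.9 ± 0.701% and 6.29 ± 0.524% (n = 2 and 2 libraries). Alveolar fibroblasts were at 20.3 ± 1.86% and 19.3 ± 0.887%, peribronchial fibroblasts at 29.1 ± 5.14% and 28.1 ± 0.310%, and smooth muscle at 3.45% and 3.56%. Endothelial cells were at 6.56% and 7.06%, epithelial cells at 1.17% and 0.707%, glia at 0.972% and 0.641%, and clusters without a name at 9.60% and 6.82%. An exact two-sided permutation test on 2 against 2 libraries cannot go below p = 0.333, so 0 of 10 classes passed it, with a smallest adjusted p of 0.667. edgeR on cell counts called 4 classes: adventitial fibroblasts (adjusted p 6.12e-05), immune cells (6.80e-05), pericytes (0.00176) and epithelial cells (0.0487). The sort sets these shares as well as the tissue does.

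Within classes, some clusters appeared almost only after HDM. In peribronchial fibroblasts, a cluster marked by Ccl7, Tnc, Lif and Timp1 held 18.7% of the class in HDM and 1.29% in PBS, and a cluster marked by Ifit1, Ifit3 and Ifit3b held 14.3% and 0.135%. A cluster marked by Acaca and Cyp2e1 held 25.8% of peribronchial fibroblasts in HDM and 52.0% in PBS. Alveolar fibroblasts split into a cluster marked by Nox4 and Nebl, with 48.1% of the class in HDM and 34.4% in PBS, and one marked by Gsta3 and Inmt with 51.9% and 65.6%. An unnamed cluster marked by Cxcl13, Saa3, Lcn2 and Hp held 2.38% of all kept cells in HDM and 0.0740% in PBS.

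**Figure D1:**
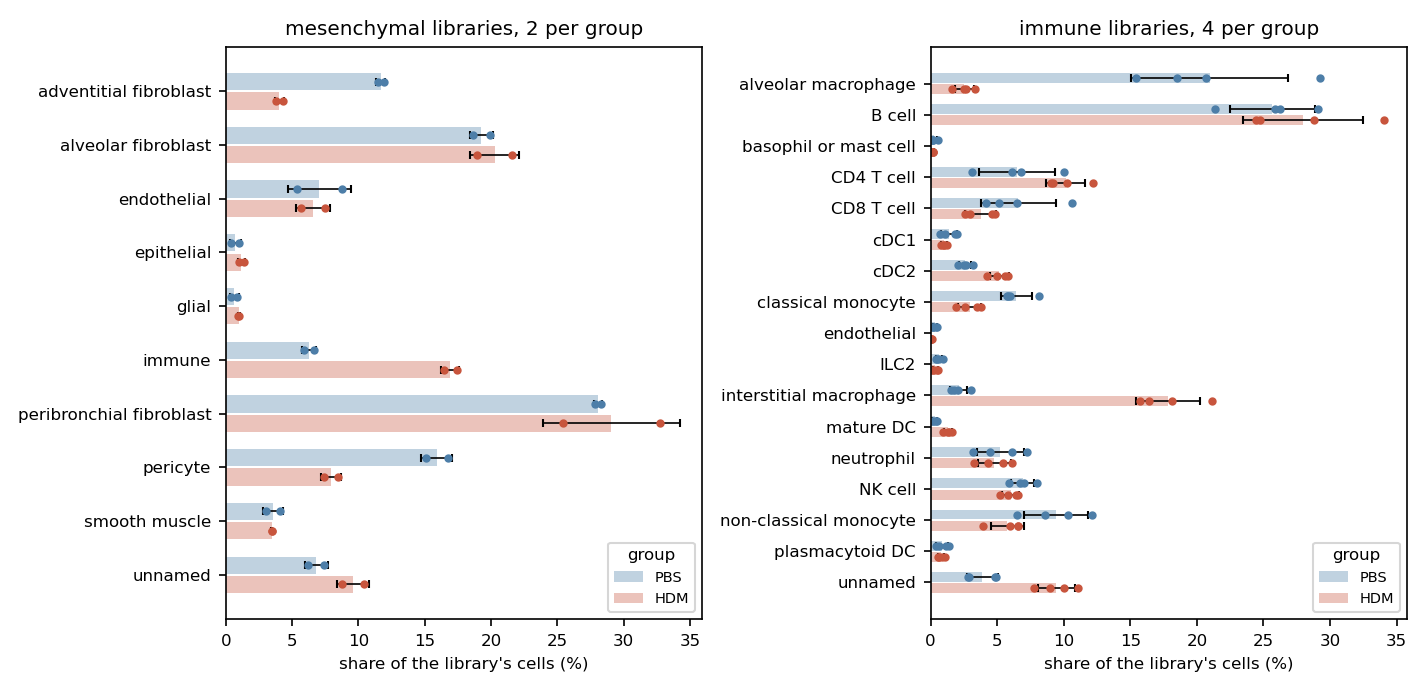
Share of kept cells (%) in each class, HDM beside PBS, in the mesenchymal libraries (left) and the immune mice (right): points are libraries or mice, bars their means and error bars SD. Alveolar macrophages drop and interstitial macrophages rise.

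Alveolar fibroblasts, the lipid-storing stroma beside the air sacs, had interferon response and complement genes among those that rose after HDM. Of 10870 genes tested, 904 rose and 559 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, n = 2 and 2 libraries). Ly6e, an interferon-induced surface protein, rose by a log2 fold change of 2.17 ± 0.16 (SE; adjusted p 5.65e-07), from 79.1 ± 7.91 to 351 ± 55.3 CPM. The lipid carrier Apod rose by 2.68 ± 0.21 (9.13e-07).

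The interferon response group had 26 of 29 alveolar fibroblast members up, 0 down and 3 not called, and the same 26 up adjusted over the list alone. Isg15, which tags proteins during antiviral responses, rose 2.63 ± 0.21 in log2, Ifi44 4.89 ± 0.39, Ifit3 2.20 ± 0.21, Oasl2 2.30 ± 0.20 and Ifi27l2a 2.04 ± 0.17. Complement and acute phase genes had 10 of 13 up and 3 not called (12 up adjusted over the list alone): Lcn2, an iron-binding acute phase protein, rose 5.33 ± 0.49, C3 1.46 ± 0.14, C4b 1.81 ± 0.18 and Cfb 1.42 ± 0.23. Among chemokines 6 of 11 rose, 1 fell and 4 were not called (8 up and 1 down adjusted over the list alone), with the T cell attractants Cxcl10 at 2.06 ± 0.27 and Cxcl9 at 4.06 ± 0.55 and the monocyte attractant Ccl2 at 1.00 ± 0.17. Of 23 fibrillar matrix genes 6 rose and 17 were not called (7 up and 1 down adjusted over the list alone), with Tnc at 1.49 ± 0.17, Fn1 at 1.06 ± 0.15 and Eln at 1.36 ± 0.20. MHC class II presentation had 4 of 7 up and 3 not called (5 up adjusted over the list alone), led by the invariant chain Cd74 at 1.60 ± 0.29, beside Ptprc over whole libraries at 157 CPM in HDM and 48.5 in PBS. The IL-4 and IL-13 response group had 3 of 14 up and 11 not called (5 up and 1 down adjusted over the list alone), among them the eosinophil attractant Ccl11 at 1.80 ± 0.38.

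Among cytokines and growth factors, 4 of 22 rose in alveolar fibroblasts, 2 fell and 16 were not called, with the same counts adjusted over the list alone. Il6 rose 0.97 ± 0.16 in log2, Csf1 1.02 ± 0.20 and Wnt5a 1.21 ± 0.25, while Fgf7, a growth factor for epithelium, fell, at −0.63 ± 0.14. Cell cycle genes had 3 of 8 down and 5 not called, also adjusted over the list alone, with the tubulin regulator Stmn1 at −0.76 ± 0.15. Immediate-early and dissociation genes had 1 up, 11 down and 10 not called of 22 (1 up and 13 down adjusted over the list alone), with Hspa1a at −1.10 ± 0.15. Glycolysis and hypoxia had 4 of 15 down and 11 not called (2 up and 5 down adjusted over the list alone), with Gapdh at −0.93 ± 0.17 and Ldha at −0.65 ± 0.15. Ifi27, Igfbp6 and 45 of 90 ribosomal protein genes also fell, Ifi27 at −1.30 ± 0.15 and Igfbp6, an IGF-binding protein, at −1.15 ± 0.14. With fry, 0 of 15 lists passed after adjustment (7 at 0.05 before adjustment), while the mixed test for change in either direction passed 11 and camera 0. Without PBS library 1 the count of changed genes was 748. Without HDM library 2 fry called 2 lists. Csf1 was not called by DESeq2 (adjusted p 0.0504), nor Ldha with doublets kept (0.0737).

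Adventitial fibroblasts, which line vessels and airways, raised complement and acute phase genes, H2-Q7 and H2-Q6 after HDM. Of 8816 genes tested, 314 rose and 160 fell (n = 2 and 2 libraries). H2-Q7, a non-classical MHC class I gene (ENSMUSG00000060550, mm10 chromosome 17, 35439155 to 35443773), rose by a log2 fold change of 6.85 ± 0.28 (adjusted p 1.59e-05), from 2.04 ± 1.53 to 273 ± 1.90 CPM, and its neighbour H2-Q6 by 7.90 ± 0.46 (8.57e-05). Csmd1, which encodes a complement regulator, rose 2.67 ± 0.17.

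Complement and acute phase genes had 8 of 13 adventitial members up and 5 not called (10 up and 1 down adjusted over the list alone). Cfb rose 2.31 ± 0.14 in log2, C3 1.49 ± 0.12, C4b 1.32 ± 0.13 and the acute phase gene Saa3 4.11 ± 0.55. This list moved up on balance with fry (adjusted p 0.0243; adjusted p = 0.13 with an estimated correlation). So did TGF-beta response genes, with 7 of 19 up and 12 not called (10 up and 1 down adjusted over the list alone; fry 0.0455; adjusted p = 0.21 with an estimated correlation), including Fn1 at 0.96 ± 0.13, Timp1 at 1.01 ± 0.16 and the contractile gene Acta2 at 1.65 ± 0.29. Cytokines and growth factors passed fry at 0.0455 (adjusted p = 0.27 with an estimated correlation), with a median log2 of 0.24 and 0 of 19 members called, also adjusted over the list alone. Interferon response had 26 of 30 up and 4 not called (28 up adjusted over the list alone), with Cxcl9 at 7.42 ± 0.47, Irf7, a regulator of type I interferon genes, at 2.56 ± 0.20, Ifit1 at 4.08 ± 0.32 and Ifi27l2a at 2.40 ± 0.15. Of 24 matrix genes 11 rose and 13 were not called (16 up adjusted over the list alone), with Col3a1 at 1.01 ± 0.14, Col5a2 at 1.10 ± 0.15, Eln at 1.41 ± 0.21 and the IL-13-induced matrix protein Postn at 1.49 ± 0.22. Of 13 chemokines 5 rose and 8 were not called (8 up and 1 down adjusted over the list alone). Vcam1, an adhesion molecule for leukocytes, rose 1.04 ± 0.17.

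Down in adventitial fibroblasts were Plac9b (−1.50 ± 0.18), Inmt (−1.28 ± 0.16), the cytokine-signal inhibitor Socs3 (−0.99 ± 0.14) and Junb (−0.82 ± 0.14). Immediate-early and dissociation genes had 4 of 22 down and 18 not called (2 up and 13 down adjusted over the list alone). Glycolysis had 3 of 14 down and 11 not called (5 down adjusted over the list alone), among them Gapdh at −0.85 ± 0.14. Cholesterol and fatty acid synthesis had 2 of 17 down and 15 not called (4 down adjusted over the list alone). Il1rl1, the IL-33 receptor, rose 3.65 ± 0.65 from 1.89 ± 0.0299 to 27.5 ± 17.4 CPM, but was not called without HDM library 1 (adjusted p 0.124). Il33, Tslp and Ccl11 were not called here, at 0.46 ± 0.19, 0.08 ± 0.22 and 0.09 ± 0.18. Without HDM library 1 fry called 1 list and without HDM library 2 it called 0. DESeq2 called 286 genes, 120 up and 166 down, in place of 474.

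In peribronchial fibroblasts, the stroma around the airways, 955 of 10045 genes rose and 816 fell (n = 2 and 2 libraries), and DESeq2 called 819. Ifi27l2a, an interferon-induced gene (ENSMUSG00000079017, mm10 chromosome 12, 103442167 to 103443680), rose by a log2 fold change of 5.79 ± 0.20 (adjusted p 1.05e-13), from 10.2 ± 3.31 to 540 ± 38.0 CPM. Complement C3 (ENSMUSG00000024164, mm10 chromosome 17, 57203970 to 57228136) rose by 4.33 ± 0.17 (8.71e-13). H2-Q7 rose by 5.35 ± 0.25 (1.32e-11), from 3.08 ± 0.197 to 128 ± 8.00 CPM.

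Interferon response genes had 30 of 31 peribronchial members up and 1 not called, with the same count adjusted over the list alone (fry adjusted p 0.0367; adjusted p = 0.15 with an estimated correlation). Cxcl9 rose 8.17 ± 0.41 in log2, Isg15 3.20 ± 0.17, Ifit1 4.63 ± 0.28 and Ifit3 4.29 ± 0.26. Complement and acute phase had 11 of 13 up and 2 not called, the same adjusted over the list alone (fry 0.0122; adjusted p = 0.069 with an estimated correlation), with C4b at 2.37 ± 0.17 and C1s1 at 2.41 ± 0.19. Fibrillar matrix genes had 17 of 24 up, 1 down and 6 not called (20 up and 1 down adjusted over the list alone; fry 0.00662; adjusted p = 0.069 with an estimated correlation): Tnc rose 1.76 ± 0.13, Col6a2 1.72 ± 0.15, Col3a1 1.49 ± 0.13, and Col1a1 1.15 ± 0.13. Smooth muscle contractile genes had 7 of 14 up and 7 not called (8 up adjusted over the list alone; fry 0.0225; adjusted p = 0.15 with an estimated correlation), with Acta2 at 1.00 ± 0.12 and the myosin kinase Mylk at 1.10 ± 0.14. The TGF-beta response had 9 of 18 up, 2 down and 7 not called (10 up and 3 down adjusted over the list alone; fry 0.0268; adjusted p = 0.15 with an estimated correlation). Cytokines and growth factors had 7 of 19 up, 2 down and 10 not called (7 up and 3 down adjusted over the list alone; fry 0.0268; adjusted p = 0.15 with an estimated correlation), with Wnt5a at 1.36 ± 0.14, Lif at 1.31 ± 0.16 and Il6 at 0.87 ± 0.13. Chemokines had 7 of 11 up, 1 down and 3 not called, also adjusted over the list alone (fry 0.0558), among them Cxcl10 at 2.12 ± 0.17, Ccl7 at 1.51 ± 0.16 and Ccl2 at 1.10 ± 0.13. Vcam1 rose 2.80 ± 0.15, and Cd74 3.34 ± 0.36.

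Cell cycle genes fell on balance in peribronchial fibroblasts, with 3 of 9 down and 6 not called (6 down adjusted over the list alone; fry 0.0122; adjusted p = 0.15 with an estimated correlation), among them Stmn1 at −1.02 ± 0.16. Immediate-early and dissociation genes fell too, with 2 up, 13 down and 7 not called of 22 (2 up and 14 down adjusted over the list alone; fry 0.0408; adjusted p = 0.15 with an estimated correlation), with Hspa1a at −1.31 ± 0.12 and Socs3 at −1.20 ± 0.14. Acaca, which encodes the first enzyme of fatty acid synthesis, fell, at −2.42 ± 0.25. The rest of cholesterol and fatty acid synthesis stayed uncalled, 16 of 17 members. The muscle gene Tcap (−1.62 ± 0.18), the ribosome assembly gene Rrs1 (−1.45 ± 0.18), the chaperone Hspa2 (−1.35 ± 0.17) and 23 of 90 ribosomal protein genes fell as well. Glycolysis and hypoxia had 3 up, 7 down and 7 not called of 17 (the same adjusted over the list alone), with Gapdh at −1.10 ± 0.14. ER stress genes were mixed, with 5 up, 3 down and 9 not called of 17 (5 up and 4 down adjusted over the list alone), Hspa5 at −0.67 ± 0.12 and Sec61b at 0.66 ± 0.14. Fry called 8 of 15 lists in all. The count was 0 without HDM library 1, without PBS library 1 or without PBS library 2, and 2 without HDM library 2.

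Pericytes, the mural cells of capillaries, had Cxcl9, Cxcl10 and MHC class II genes among those that rose after HDM. Of 7924 genes tested, 346 rose and 198 fell (n = 2 and 2 libraries). Cxcl9 (ENSMUSG00000029417, mm10 chromosome 5, 92321347 to 92328079) rose by a log2 fold change of 8.67 ± 0.48 (adjusted p 1.38e-07), from 0.525 ± 0.743 to 339 ± 98.9 CPM, and the immunity-related GTPase Iigp1 by 2.74 ± 0.18 (4.29e-07). Interferon response genes had 25 of 28 up and 3 not called (26 up adjusted over the list alone), with Ifi27l2a at 4.39 ± 0.25, Cxcl10 at 3.95 ± 0.28 and Ly6e at 3.73 ± 0.28. MHC class II presentation had 4 of 6 up and 2 not called, also adjusted over the list alone, with Cd74 at 4.30 ± 0.47 and H2-Aa at 4.22 ± 0.60, beside the Ptprc levels given above. Osteopontin (Spp1), a secreted matrix phosphoprotein, fell, at −1.37 ± 0.12, and the light chain Myl9 at −1.14 ± 0.19. Of 19 matrix genes 2 rose, 2 fell and 15 were not called (4 up and 3 down adjusted over the list alone), and Postn stayed at 3818 ± 257 and 3910 ± 23.4 CPM in HDM and PBS. The alveolar fibroblast and lipofibroblast group had 2 of 12 down and 10 not called (3 down adjusted over the list alone). With fry, 0 of 15 lists passed (5 at 0.05 before adjustment; 6 with the mixed test; 0 with camera). These calls rest on the PBS libraries: without PBS library 2 the count was 0 genes, and each called gene named here had an adjusted p of 0.333 or more. Without PBS library 1 the count was 74 (56 up and 18 down). DESeq2 called 176.

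In smooth muscle 123 of 5223 genes rose and 115 fell (n = 2 and 2 libraries). Ifi27l2a rose by a log2 fold change of 4.45 ± 0.37 (adjusted p 1.48e-06), from 71.1 ± 59.9 to 1294 ± 412 CPM, and C3 by 3.58 ± 0.35 (7.86e-06), from 27.9 ± 14.0 to 296 ± 46.5 CPM. Interferon response genes had 16 of 23 up and 7 not called (19 up adjusted over the list alone), with Cxcl9 at 6.27 ± 0.64 and Ifit1 at 3.60 ± 0.43. Of 23 matrix genes 8 rose and 15 were not called (13 up adjusted over the list alone), among them Fn1 at 1.67 ± 0.24, Col6a3 at 1.50 ± 0.23 and Col6a2 at 1.58 ± 0.25. Contractile genes had 3 of 15 up and 12 not called (3 up and 1 down adjusted over the list alone), with Mylk at 1.42 ± 0.21. Acta2 itself was not called, at 5204 ± 161 and 4514 ± 1413 CPM. Acaca fell, at −2.64 ± 0.25, the nuclear envelope gene Syne3 at −2.32 ± 0.32, and Stac2 was at least 28.7-fold lower, from 102 ± 27.1 CPM to 0. Immediate-early and dissociation genes had 12 of 22 down and 10 not called (16 down adjusted over the list alone), with Hspa1a at −1.41 ± 0.17 and Hspa1b at −1.21 ± 0.18. Fry called 0 of 14 lists (5 at 0.05 before adjustment), the mixed test 10 and camera 0. The gene count was 143 without HDM library 1, 150 without HDM library 2 and 360 without PBS library 1. DESeq2 called 83.

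In endothelial cells, sorted along with the stroma, 25 of 8048 genes rose and 28 fell (n = 2 and 2 libraries). Ifi27l2a rose by a log2 fold change of 1.60 ± 0.21 (adjusted p 0.00944), from 65.7 ± 7.98 to 198 ± 22.3 CPM, Ifi44 by 1.45 ± 0.22, Ifit1 by 1.58 ± 0.31 and Cxcl9 by 5.37 ± 0.86. Interferon response genes had 4 of 30 up and 26 not called (13 up adjusted over the list alone). Cxcl14 fell, at −2.58 ± 0.34, Inmt at −2.10 ± 0.36 and the matrix proteoglycan Bgn at −1.46 ± 0.25, and Bgn was not called without PBS library 1 (adjusted p 0.0792). With doublets kept, Bgn turned to 0.25 (0.529) and Cxcl14 was at −0.87 (0.0876), neither of them called. Fry called 0 of 15 lists (1 at 0.05 before adjustment), the mixed test 0 and camera 0. The gene count was 248 without HDM library 1, 310 without HDM library 2, 368 without PBS library 2, and it was 80 with doublets kept (55 up and 25 down) and 2 at a mitochondrial limit of 5%.

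Epithelial cells gave 2930 testable genes, of which 19 rose and 1 fell (n = 2 and 2 libraries). Ifi27l2a rose by a log2 fold change of 5.22 ± 0.52 (adjusted p 3.02e-05), from 50.1 ± 70.8 to 2493 ± 213 CPM, and C3 by 3.55 ± 0.60 (0.00524), from 21.1 ± 1.46 to 251 ± 16.5 CPM. H2-Q7 was at least 12.9-fold higher and the lysozyme Lyz1 at least 33.0-fold, each with 0 counts in PBS. Interferon response genes had 8 of 11 up and 3 not called (8 up and 1 down adjusted over the list alone; fry 0.0214; adjusted p = 0.11 with an estimated correlation). Fry called this 1 list of 12, and 0 without any 1 of the libraries (HDM library 1, HDM library 2, PBS library 1 or PBS library 2). The gene count was 56 without PBS library 1 and 85 without PBS library 2. DESeq2 called 4, with Ifi27l2a at an adjusted p of 0.342 and H2-Q7 at 0.116.

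Leukocytes that came through the mesenchymal sort had higher Ctla4 and Tnfrsf4 and lower Pf4, F13a1 and Mrc1 after HDM. The mix of leukocytes differed: a cluster marked by Icos and Ctla4 held 15.1% of the class in HDM and 4.56% in PBS, one marked by Igkc 34.3% and 25.3%, Gzma 17.6% and 16.1%, C1qb 21.8% and 26.6%, S100a8 6.17% and 14.9%, and Chil3 5.11% and 12.5%. Of 9803 genes tested, 272 rose and 439 fell (n = 2 and 2 libraries). The T cell checkpoint Ctla4 rose by a log2 fold change of 3.60 ± 0.34 (adjusted p 0.000579), from 24.3 ± 16.1 to 314 ± 71.4 CPM, and Tnfrsf4, the OX40 costimulator, by 2.87 ± 0.26. The plasma cell genes Ighg2b and Jchain were at least 46.8-fold and at least 109-fold higher, with 0 counts in PBS. The macrophage genes Pf4 (−4.12 ± 0.26), F13a1 (−3.66 ± 0.25) and Mrc1 (−2.10 ± 0.18) fell. Cell cycle genes had 9 of 23 up and 14 not called (15 up adjusted over the list alone), with Ube2c at 4.03 ± 0.52 (not called with doublets kept, adjusted p 0.0726) and Birc5 at 2.27 ± 0.40. Chemokines had 1 up, 8 down and 9 not called of 18 (2 up and 11 down adjusted over the list alone), with Ccl12 at −2.52 ± 0.22, Ccl2 at −2.14 ± 0.24 and Ccl3 at −1.75 ± 0.24. Interferon response genes had 14 of 31 up and 17 not called (25 up adjusted over the list alone), and the IL-4 and IL-13 response 1 up, 6 down and 13 not called of 20 (2 up and 9 down adjusted over the list alone), with Mgl2 at −2.58 ± 0.27. Fry called 0 of 15 lists (3 at 0.05 before adjustment), the mixed test 12 and camera 0. Without HDM library 1 the count of genes was 467. DESeq2 called 410.

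**Figure D2:**
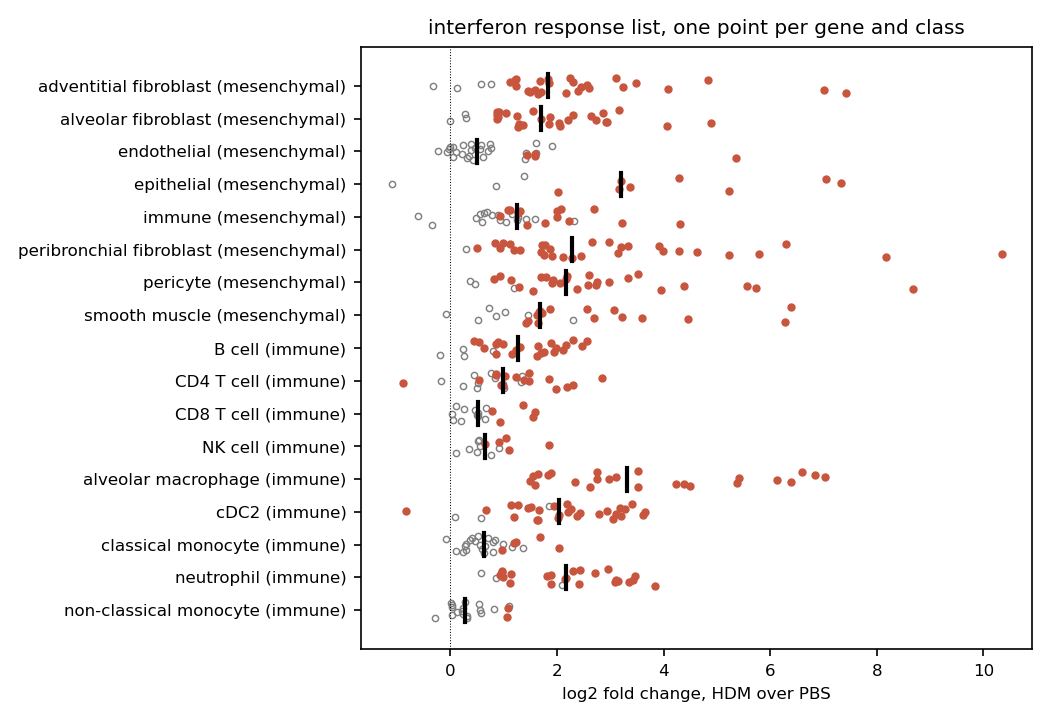
Log2 fold change, HDM over PBS, of each member of the interferon response list in every class tested at 20 cells. Filled points passed an adjusted p of 0.05, open points did not, and the bar is the class median, above 0 in every class shown.

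Alveolar and adventitial fibroblasts differed in part of their response, tested as an interaction of class and treatment over 10990 genes. The log2 change was higher in adventitial fibroblasts for 29 genes and in alveolar ones for 28, and 274 genes were called in both classes with the same sign. Acta2 differed by a log2 of 2.33 ± 0.32 (adjusted p 0.00254), at −0.68 in alveolar and 1.65 in adventitial fibroblasts, and Csmd1 by 1.90 ± 0.32, at 0.77 and 2.67. H2-Q7 rose in both classes, by 3.02 and 6.85, and more in adventitial fibroblasts. Ifi203, an interferon-inducible DNA sensor of the p200 family, rose 3.17 in alveolar fibroblasts and was at 0.86 in adventitial ones, a difference of −2.30 ± 0.34 (adjusted p 0.00559). The related Ifi211 differed by −1.85 ± 0.29, at 2.26 and 0.38, and the collagen Col23a1 by −1.45 ± 0.23, at 0.54 and −0.98. The count was 28 without HDM library 1, 92 without PBS library 1 and 129 without PBS library 2. Acta2 and Ifi211 were not called without HDM library 2 (adjusted p 0.0664 and 0.0798), and H2-Q7, Csmd1 and Col23a1 were not called without HDM library 1 (0.0592, 0.0631 and 0.0604), nor H2-Q7 without PBS library 2 (0.136).

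Genes known from allergic lung stroma were followed in every class where they could be tested. Saa3 rose in 4 of 4 classes, C3 in 5 of 7, Col1a1, Acta2 and Vcam1 in 3 of 7 each, Postn in 2 of 7, and Timp1 and Il6 in 2 of 5 each. The chemokine Ccl2 rose in 2 of 7 classes, both fibroblast classes, and fell in the immune cells. Tslp, an epithelial-type alarmin, was called in 1 of 6 classes, alveolar fibroblasts, at a log2 of 0.56 ± 0.16, from 62.9 ± 10.0 to 90.9 ± 3.02 CPM, and it was not called without HDM library 2 or PBS library 2 (adjusted p 0.0842 and 0.349), nor by DESeq2 (0.182). The alarmin Il33 (2 classes tested), Cxcl12 (5) and the IL-4 receptor chain Il4ra (5) were called in 0 classes, and Il13ra2 could be tested in 0 classes.

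In the immune libraries, alveolar macrophages were the largest loss and interstitial macrophages the largest gain after HDM. Alveolar macrophages were 2.53 ± 0.727% of kept cells in HDM and 21.0 ± 5.90% in PBS, and interstitial macrophages 17.8 ± 2.42% and 2.10 ± 0.649% (n = 4 and 4 mice). Type 2 conventional dendritic cells (cDC2) were at 5.16 ± 0.711% and 2.60 ± 0.449%, mature dendritic cells at 1.31 ± 0.269% and 0.301 ± 0.164%, and classical monocytes at 2.93 ± 0.862% and 6.42 ± 1.16%. Unnamed clusters held 9.45 ± 1.42% and 3.87 ± 1.16%. All of these classes and the few endothelial cells reached an exact two-sided permutation p of 0.0286, the smallest possible with 4 against 4 mice, and an adjusted p of 0.0694, so 0 of 17 classes passed after adjustment. edgeR on cell counts called 10 classes, 5 up and 5 down. CD4 T cells were at 10.2% in HDM and 6.52% in PBS (exact permutation p 0.0857), CD8 T cells at 3.75% and 6.59% (0.114) and non-classical monocytes at 5.76% and 9.39% (0.0857). B cells were at 28.0% and 25.7%, without an unnamed cluster that held 8 of 8 B-cell markers (6.09% and 1.40%), NK cells at 6.02% and 6.91% and neutrophils at 4.79% and 5.25%.

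A cluster marked by Ctsk, Ch25h and Ccnb2 held 86.5% of alveolar macrophages in HDM and 7.18% in PBS. CD4 T cells split into a cluster marked by Ctla4, Tnfrsf4 and Il10, with 61.1% of the class in HDM and 14.8% in PBS, and one marked by Igfbp4 and Lef1, with 38.9% and 85.2%. B cells held clusters led by Gm31243 (55.1% in HDM, 5.72% in PBS) and Ighd (37.2% and 68.6%), both marked by Ighd and Fcer2a. A neutrophil cluster marked by Acod1, Csf1 and Slfn4 held 56.5% of the class in HDM and 8.38% in PBS. Unnamed clusters were marked by Fcrl5 (the B-like one, 6.09% and 1.40% of all kept cells), Il23r and Zbtb16 (2.87% and 2.41%) and the plasma cell genes Ighg2b and Jchain (0.496% and 0.0517%). When cells of either compartment were clustered again without the genes called below, all 27 class shares stayed uncalled. In the mesenchymal libraries the permutation test could not have called any. The lists' median and mean log2 and their test differed in sign in 39 of 266 tests, and in 0 of the 64 that fry called. Class values below mix change within cells with change in the cells that carry the class name, and treatment with capture.

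**Figure D3:**
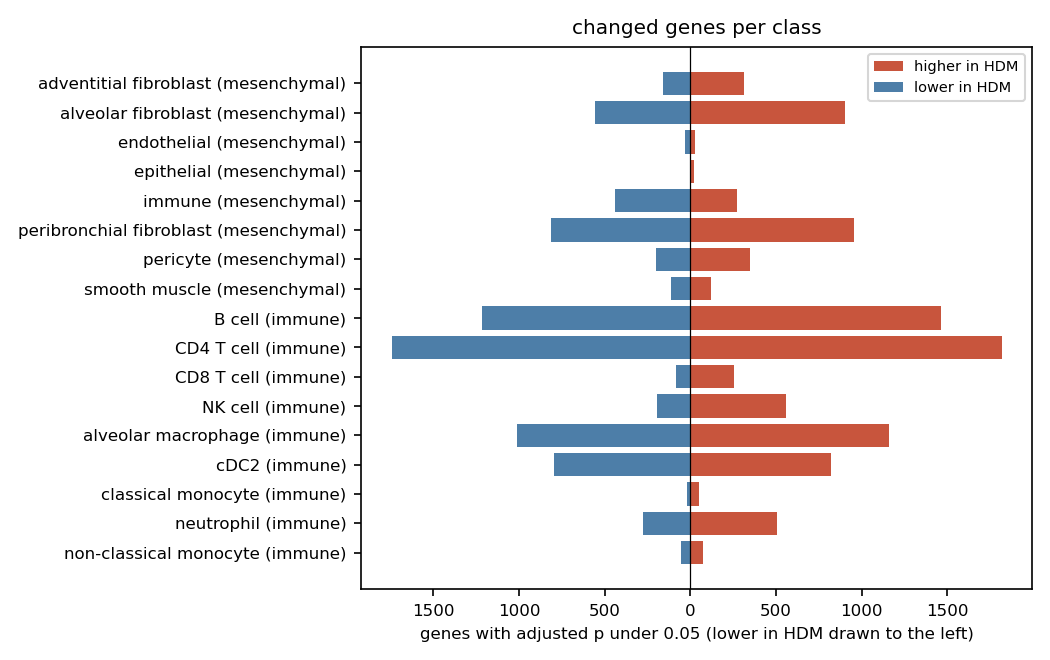
Number of genes higher (right) and lower (left) in HDM at an adjusted p of 0.05 (edgeR) in each class tested at 20 cells. CD4 T cells have the longest bars and epithelial cells the shortest.

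Alveolar macrophages, the resident phagocytes of the air sacs, carried a broad interferon response after HDM. Of 8438 genes tested, 1162 rose and 1010 fell (edgeR quasi-likelihood test, n = 4 and 4 mice). Irf7 (ENSMUSG00000025498, mm10 chromosome 7, 141262706 to 141266481) rose by a log2 fold change of 6.12 ± 0.29 (SE; adjusted p 1.76e-09), from 3.23 ± 2.48 to 180 ± 57.5 CPM, and Oasl2 by 7.03 ± 0.35 (2.76e-09), from 1.29 ± 1.21 to 153 ± 49.9 CPM. All 24 interferon response members rose, also adjusted over the list alone (fry adjusted p 0.000719), and this was the only list of 16 that camera called with an estimated correlation (adjusted p = 0.021).

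Chemokines rose on balance in alveolar macrophages, with 5 of 9 up, 1 down and 3 not called, also adjusted over the list alone (fry 0.000768; adjusted p = 0.06 with an estimated correlation): Ccl9 rose 2.81 ± 0.19 in log2, Cxcl16 3.80 ± 0.37 and Ccl3 1.89 ± 0.30. Monocyte-derived macrophage genes had 5 of 10 up and 5 not called (6 up adjusted over the list alone; fry 0.00074; adjusted p = 0.06 with an estimated correlation), with the lipid receptor Trem2 at 1.67 ± 0.19, Gpnmb at 1.49 ± 0.17 and Cd63 at 2.26 ± 0.16, beside interstitial macrophage markers over whole libraries at 2112 CPM in HDM and 216 in PBS. Neutrophil granule and activation genes had 7 of 9 up, 1 down and 1 not called, also adjusted over the list alone (fry 0.000768; adjusted p = 0.06 with an estimated correlation), with Wfdc17 at 2.63 ± 0.29 and S100a8 at 1.51 ± 0.24. Glycolysis and hypoxia had 8 of 14 up and 6 not called (11 up and 1 down adjusted over the list alone; fry 0.00147; adjusted p = 0.16 with an estimated correlation), with Pgam1 at 1.10 ± 0.09. MHC class II presentation had 5 of 9 up and 4 not called (6 up adjusted over the list alone; fry 0.021; adjusted p = 0.42 with an estimated correlation), with the protease Ctss at 1.06 ± 0.13 and H2-Eb1 at 1.89 ± 0.41. Here immediate-early and dissociation genes rose, 8 of 21 with 13 not called, also adjusted over the list alone (fry 0.021; adjusted p = 0.47 with an estimated correlation), with Fos at 1.01 ± 0.12.

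Alveolar macrophage identity genes were split, with 5 of 20 up, 5 down and 10 not called, also adjusted over the list alone, a mixed test p of 4.31e-05 and a median log2 of −0.08. The bone and matrix protease Ctsk rose 2.05 ± 0.16, and the carbonic anhydrase Car4 1.30 ± 0.20. The fatty acid binding protein Fabp1 fell, at −2.77 ± 0.32, the ribonuclease Ear1 at −1.17 ± 0.15, and the fatty acid enzymes Acaa1b at −2.97 ± 0.26 and Elovl6 at −1.72 ± 0.22. Cpne5 fell, at −2.60 ± 0.19. Cell cycle genes had 8 of 21 up, 1 down and 12 not called, also adjusted over the list alone, with Ccnb2 at 1.77 ± 0.26. The chitinase-like protein Chil3 rose 0.88 ± 0.24, from 13975 ± 3508 to 25632 ± 11142 CPM, and the cytokine Il1b 1.17 ± 0.28, and neither was called without HDM mouse 2 (adjusted p 0.0552 and 0.0533). Chil3 was not called by DESeq2 (0.0752) or with doublets kept (0.0972).

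Interstitial macrophages, found in the lung tissue, were too few in PBS for the planned minimum of 20 cells per library. At a minimum of 10 cells, a choice made after the counts were seen, 313 of 8559 genes rose and 297 fell (n = 4 and 4 mice). Ly6a, a surface protein induced by interferon, rose by a log2 fold change of 5.57 ± 0.35 (adjusted p 4.13e-06), from 17.9 ± 10.7 to 736 ± 207 CPM, the matrix protein Spon1 by 4.23 ± 0.40, and Saa3 by 5.05 ± 0.62. Complement and acute phase genes had 3 of 9 up, 1 down and 5 not called (5 up and 1 down adjusted over the list alone; fry 0.0149; adjusted p = 0.14 with an estimated correlation), with Cfb at 3.17 ± 0.32. Chemokines had 4 up, 4 down and 7 not called of 15 (6 up and 5 down adjusted over the list alone; fry 0.0149; adjusted p = 0.14 with an estimated correlation), with Ccl8 at 3.72 ± 0.40, Ccl5 at 3.46 ± 0.43, Ccl6 at −1.72 ± 0.22 and Cxcl2 at −2.15 ± 0.40. Of 21 immediate-early and dissociation genes 14 fell and 7 were not called (16 down adjusted over the list alone; fry 0.03; adjusted p = 0.14 with an estimated correlation), with Egr1 at −3.38 ± 0.37 and Hspa1a at −2.25 ± 0.26. Alveolar macrophage identity genes had 1 up, 4 down and 9 not called of 14 (1 up and 5 down adjusted over the list alone; fry 0.0414; adjusted p = 0.14 with an estimated correlation), with the lipid receptor Cd36 at −2.68 ± 0.31 and Ear2 at −5.36 ± 0.69, beside alveolar macrophage markers over whole libraries at 272 CPM in HDM and 2260 in PBS. Interferon response had 9 of 31 up and 22 not called (16 up adjusted over the list alone), and cholesterol and fatty acid synthesis 4 of 14 down and 10 not called (9 down adjusted over the list alone). The alternative activation gene Mgl2 fell, at −2.68 ± 0.39 and Retnla at −3.28 ± 0.68, Retnla not without HDM mouse 4 (adjusted p 0.0533). The gene count was 370, 383, 343 and 355 without HDM mouse 1, 2, 3 and 4, 403 without PBS mouse 2 and 1074 without PBS mouse 3. DESeq2 called 982 (424 up and 558 down). Fry called 4 of 18 lists, 1 without HDM mouse 3 and 2 without PBS mouse 3.

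The interaction of macrophage class and treatment, also at 10 cells, covered 9200 genes. The log2 change was higher in interstitial than in alveolar macrophages for 119 genes and lower for 323, and 254 genes were called in both classes with the same sign. Rsad2, an antiviral enzyme induced by interferon, differed by a log2 of −7.95 ± 0.65 (adjusted p 2.22e-06), at 6.84 in alveolar and −1.65 in interstitial macrophages. Mmp12, the macrophage elastase, differed by −6.42 ± 0.65 (1.25e-05), up 2.54 in alveolar and down −3.17 in interstitial macrophages. The nucleotide kinase Cmpk2 differed by −6.46 ± 1.06, at 5.26 and −1.87. In the other direction were the chemokine Ccl5, different by 3.24 ± 0.51 at 0.40 and 3.46, and the sialic acid receptor Siglec1, different by 2.76 ± 0.57 at 0.32 and 3.08. Siglec1 was not called without PBS mouse 3 (adjusted p 0.0768), and the count was 285 without HDM mouse 2.

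B cells raised MHC class II, protein folding, interferon and ribosomal protein genes after HDM. Of 8697 genes tested, 1465 rose and 1214 fell (n = 4 and 4 mice). The vesicle protein Syngr2 rose by a log2 fold change of 1.67 ± 0.11 (adjusted p 2.91e-10), from 43.5 ± 7.90 to 145 ± 14.3 CPM, and Ly6a by 1.88 ± 0.14 (1.04e-09), from 118 ± 25.4 to 422 ± 83.7 CPM. MHC class II presentation had 10 of 12 up and 2 not called, also adjusted over the list alone (fry 0.000162; adjusted p = 0.083 with an estimated correlation): H2-Aa rose 0.72 ± 0.06, H2-Ab1 0.75 ± 0.06 and Cd74 0.50 ± 0.04. ER stress and folding genes had 12 of 17 up and 5 not called (13 up adjusted over the list alone; fry 0.000162; adjusted p = 0.083 with an estimated correlation), with Manf at 1.04 ± 0.09 and Ssr4 at 1.07 ± 0.10. Interferon response had 22 of 26 up and 4 not called (23 up adjusted over the list alone; fry 0.0029; adjusted p = 0.16 with an estimated correlation), with Ifi27l2a at 1.70 ± 0.12, Zbp1 at 2.30 ± 0.24 and the immunoproteasome subunit Psmb8 at 0.98 ± 0.08. Of 90 ribosomal protein genes tested 85 rose and 3 fell.

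Glycolysis and hypoxia also rose on balance in B cells, with 4 of 14 up and 10 not called (7 up adjusted over the list alone; fry 0.00136; adjusted p = 0.22 with an estimated correlation), with Ldha at 1.07 ± 0.11. Cell cycle genes had 3 of 11 up and 8 not called, also adjusted over the list alone (fry 0.0341; adjusted p = 0.71 with an estimated correlation), with the nuclear transport GTPase Ran at 1.04 ± 0.09. The type 2 lymphocyte group had 2 of 5 up and 3 not called, also adjusted over the list alone (fry 0.00776; adjusted p = 0.39 with an estimated correlation), with Plac8 at 0.62 ± 0.08 and the TSLP receptor Crlf2 at 0.55 ± 0.14. Naive and central memory genes had 5 of 8 down and 3 not called, also adjusted over the list alone (fry 0.00136; adjusted p = 0.17 with an estimated correlation), with Foxp1 at −0.30 ± 0.05 and the trafficking regulator Klf2 at −0.50 ± 0.09. Alveolar macrophage identity genes had 3 of 6 down and 3 not called, also adjusted over the list alone (fry 0.000473; adjusted p = 0.16 with an estimated correlation), with Chil3 at −2.20 ± 0.18, from 50.7 ± 7.07 to 10.8 ± 2.41 CPM. Over whole immune libraries markers of alveolar macrophages summed to 272 ± 53.9 CPM in HDM and 2260 ± 321 in PBS. The B-cell activation and antibody group had 4 up, 2 down and 5 not called of 11, also adjusted over the list alone, with the activation enzyme Cd38 at 0.61 ± 0.12, the plasma cell regulator Xbp1 at 0.64 ± 0.14 and Sdc1 at −1.46 ± 0.28. Lymphocyte activation had 2 up, 4 down and 5 not called of 11, also adjusted over the list alone, with Cd69 at 1.06 ± 0.11 and Cd44 at −0.73 ± 0.12. Txnip fell, at −1.24 ± 0.13, and the tumour suppressor Fhit at −1.17 ± 0.17. Fry called 8 of 14 lists and camera 0.

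In CD4 T cells, whose clusters differed between groups, naive genes fell and activation and regulatory T cell genes rose. Of 8006 genes tested, 1817 rose and 1744 fell (n = 4 and 4 mice). All 13 naive and central memory genes fell, also adjusted over the list alone (fry 9.47e-05; adjusted p = 0.052 with an estimated correlation): Lef1 at a log2 fold change of −2.34 ± 0.11 (adjusted p 2.97e-09), from 1913 ± 250 to 374 ± 24.7 CPM, Satb1 at −1.69 ± 0.11 and the egress receptor S1pr1 at −1.64 ± 0.12. Lymphocyte activation had 17 of 21 up, 2 down and 2 not called, also adjusted over the list alone (fry 0.000406; adjusted p = 0.093 with an estimated correlation), with Lgals1 at 2.56 ± 0.18, and S100a6 at 2.81 ± 0.24. Regulatory T cell genes had 12 of 14 up and 2 not called, also adjusted over the list alone (fry 0.00772; adjusted p = 0.25 with an estimated correlation): Ctla4 rose 2.65 ± 0.22, Capg 2.48 ± 0.22, Tnfrsf4 1.99 ± 0.24 and the lineage factor Foxp3 1.15 ± 0.27.

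The suppressive cytokine Il10 (ENSMUSG00000016529, mm10 chromosome 1, 131019845 to 131024974) rose by a log2 of 5.54 ± 0.51 in CD4 T cells (adjusted p 6.66e-07), from 8.54 ± 14.2 to 235 ± 93.0 CPM, and the type 2 lymphocyte group that holds it had 8 of 12 up and 4 not called, also adjusted over the list alone (fry 0.00983; adjusted p = 0.25 with an estimated correlation), with the neuropeptide Calca at 4.88 ± 0.63 and Crlf2 at 1.32 ± 0.19. The group's type 2 regulator Gata3 was not called, at 122 ± 12.4 and 129 ± 74.0 CPM, nor Il13, at 34.1 ± 19.2 and 16.7 ± 33.4 CPM. Cytotoxicity genes had 4 up, 1 down and 5 not called of 10, also adjusted over the list alone (fry 0.00772; adjusted p = 0.25 with an estimated correlation), with granzyme Gzmb at 3.88 ± 0.39, Nkg7 at 2.45 ± 0.35 and Ifng at 1.88 ± 0.49. The checkpoint Havcr2 rose 4.05 ± 0.37 and the metalloproteinase Adam12 3.96 ± 0.33.

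Cell cycle genes had 23 of 24 up in CD4 T cells and 1 not called (24 up adjusted over the list alone; fry 0.00154; adjusted p = 0.22 with an estimated correlation), with Stmn1 at 1.44 ± 0.21 and Ube2c at 2.24 ± 0.34. Glycolysis had 8 of 13 up and 5 not called, also adjusted over the list alone (fry 0.000164; adjusted p = 0.13 with an estimated correlation), with Gapdh at 1.26 ± 0.11. ER stress genes had 10 up, 1 down and 6 not called of 17 (11 up and 1 down adjusted over the list alone; fry 0.00132; adjusted p = 0.25 with an estimated correlation). Interferon response had 15 up, 1 down and 11 not called of 27 (17 up and 1 down adjusted over the list alone; fry 0.0125; adjusted p = 0.32 with an estimated correlation), with Bst2 at 1.97 ± 0.18. MHC class II had 5 of 7 up and 2 not called (6 up adjusted over the list alone; fry 0.0272; adjusted p = 0.4 with an estimated correlation), with Cd74 at 2.66 ± 0.51. Alveolar macrophage identity had 4 up and 2 down of 6, also adjusted over the list alone (fry 0.0128; adjusted p = 0.43 with an estimated correlation), with the lipid droplet gene Plin2 at 2.45 ± 0.22, Fabp5 at 2.71 ± 0.33 and Chil3 at −2.36 ± 0.26. Monocyte-derived macrophage genes had 2 up, 1 down and 3 not called of 6, also adjusted over the list alone (fry 0.0431; adjusted p = 0.46 with an estimated correlation), with the chemokine receptor Ccr2 at 2.97 ± 0.28. Over whole immune libraries markers were at 2112 CPM in HDM and 216 in PBS for interstitial macrophages, 272 and 2260 for alveolar ones and 2049 and 1495 for B cells. Rras2, a small GTPase, fell, at −2.70 ± 0.19. Of 89 ribosomal protein genes 6 rose and 25 fell. Fry called 12 of 16 lists and camera 0.

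NK cells gained killing and activation genes after HDM. Of 5301 genes tested, 556 rose and 195 fell (n = 4 and 4 mice), and DESeq2 called 457. The chemokine Ccl5 rose by a log2 fold change of 0.93 ± 0.07 (adjusted p 3.90e-12), from 12203 ± 808 to 23333 ± 2231 CPM, and granzyme Gzma by 0.78 ± 0.08 (9.34e-09). Cytotoxicity genes had 7 of 13 up and 6 not called, also adjusted over the list alone (fry 0.000193; adjusted p = 0.019 with an estimated correlation), with Gzmb at 0.81 ± 0.11. Lymphocyte activation had 8 of 12 up and 4 not called (9 up adjusted over the list alone; fry 0.000341; adjusted p = 0.0086 with an estimated correlation), with S100a6 at 1.18 ± 0.12 and S100a11 at 1.38 ± 0.18. The regulatory T cell group had 5 of 6 up and 1 not called, also adjusted over the list alone (fry 0.000341; adjusted p = 0.048 with an estimated correlation), with the receptors Tigit at 1.40 ± 0.34 and Tnfrsf18 at 0.90 ± 0.23. Interferon response had 5 of 13 up and 8 not called (8 up adjusted over the list alone; fry 0.00224; adjusted p = 0.057 with an estimated correlation), with Isg15 at 1.85 ± 0.37. Monocyte-derived macrophage genes had 4 of 6 up and 2 not called (fry 0.00176; adjusted p = 0.078 with an estimated correlation), beside interstitial macrophage markers over whole libraries at 2112 CPM in HDM and 216 in PBS, glycolysis 2 of 11 up and 9 not called (fry 0.0124; adjusted p = 0.25 with an estimated correlation) and cell cycle 3 of 7 up and 4 not called (fry 0.0468; adjusted p = 0.22 with an estimated correlation). Naive and central memory genes had 1 up, 3 down and 4 not called of 8 (fry 0.0393; adjusted p = 0.22 with an estimated correlation), with Lef1 at −0.96 ± 0.17. Adjusted over the list alone the counts in these groups were 4, 2 and 5 up, and 1 up with 4 down. Plac8 rose 3.87 ± 0.49, the vessel growth factor Angpt1 fell, at −1.25 ± 0.23, and 75 of 84 ribosomal protein genes rose.

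In CD8 T cells 255 of 4523 genes rose and 83 fell (n = 4 and 4 mice), and 68 of 85 ribosomal protein genes rose. Ifi27l2a rose by a log2 fold change of 1.55 ± 0.14 (adjusted p 1.15e-08), from 256 ± 46.4 to 759 ± 191 CPM, and the fatty acid elongase Elovl6 by 2.09 ± 0.23 (5.67e-08). Interferon response had 5 of 16 up and 11 not called (6 up adjusted over the list alone; fry 0.00367; adjusted p = 0.022 with an estimated correlation), with Psmb8 at 0.77 ± 0.14 and Bst2 at 0.94 ± 0.20. Immediate-early genes had 4 of 17 up and 13 not called (5 up and 2 down adjusted over the list alone), with Junb at 0.76 ± 0.11. The integrin chain Itga6 fell, at −1.15 ± 0.18, Lef1 at −0.48 ± 0.08 and Chil3 at −2.19 ± 0.47. Changed genes numbered 821 with doublets kept, 809 at a mitochondrial limit of 5% and 844 at Leiden resolution 2. Fry called 1 list of 10 in all libraries and 2 without HDM mouse 1 or PBS mouse 1.

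The cDC2, which present antigen to T cells, raised interferon genes and lowered cytokine genes after HDM. Of 7550 genes tested, 820 rose and 795 fell (n = 4 and 3 mice). Ly6a rose by a log2 fold change of 6.17 ± 0.45 (adjusted p 1.40e-05), from 4.64 ± 5.42 to 442 ± 120 CPM, and Fabp5 by 4.68 ± 0.43 (6.46e-05), from 62.4 ± 54.8 to 1810 ± 356 CPM. Interferon response had 27 of 31 up, 1 down and 3 not called (28 up and 1 down adjusted over the list alone; fry 0.00282; adjusted p = 0.12 with an estimated correlation), with Zbp1 at 3.40 ± 0.27 and Oasl2 at 3.18 ± 0.36. Cytokines and growth factors had 5 of 8 down and 3 not called, also adjusted over the list alone (fry 0.00282; adjusted p = 0.13 with an estimated correlation), with Tnf at −2.47 ± 0.30, Il1a at −2.71 ± 0.45 and Tgfb1 at −0.82 ± 0.17. Immediate-early and dissociation genes had 16 of 21 down and 5 not called (19 down adjusted over the list alone; fry 0.0441; adjusted p = 0.46 with an estimated correlation), with Egr1 at −2.94 ± 0.22, and Nr4a1 at −1.65 ± 0.17. Chemokines had 4 up, 6 down and 3 not called of 13, also adjusted over the list alone: Cxcl9 rose 3.06 ± 0.48, Ccl5 3.27 ± 0.48 and Cxcl10 1.64 ± 0.28, while the Th2 attractant Ccl17 fell, at −2.05 ± 0.42. The IL-33 receptor Il1rl1 fell, at −4.73 ± 0.42, and Mgl2 at −1.83 ± 0.27. Ccl22 was called at −2.56 ± 0.77 but not without PBS mouse 2 (adjusted p 0.488) or HDM mouse 1, 2 or 3 (0.0795, 0.0881 and 0.0787). The gene count was 1031 without PBS mouse 2.

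Neutrophils raised chemokine and interferon genes after HDM. Of 3249 genes tested, 505 rose and 279 fell (n = 4 and 3 mice). Ccl3 rose by a log2 fold change of 4.69 ± 0.69 (adjusted p 0.000342), from 76.2 ± 124 to 2190 ± 528 CPM, and Cxcl2 by 1.80 ± 0.26 (0.000302), from 1906 ± 770 to 6633 ± 1536 CPM, in a chemokine list with 3 up, 1 down and 2 not called of 6 (4 up and 1 down adjusted over the list alone; fry 0.0463; adjusted p = 0.47 with an estimated correlation). Interferon response had 23 of 26 up and 3 not called (25 up adjusted over the list alone; fry 0.0243; adjusted p = 0.32 with an estimated correlation), with Bst2 at 3.84 ± 0.41 and Ifit3 at 3.43 ± 0.44. MHC class II had 5 of 6 up and 1 not called, also adjusted over the list alone (fry 0.0463; adjusted p = 0.32 with an estimated correlation), with Ctss at 2.29 ± 0.29. Monocyte-derived macrophage genes had 5 of 8 up and 3 not called (6 up adjusted over the list alone; fry 0.031; adjusted p = 0.32 with an estimated correlation), with Gpnmb at 6.48 ± 0.90, and alveolar macrophage identity 3 up, 1 down and 3 not called of 7 (fry 0.031; adjusted p = 0.5 with an estimated correlation). Over whole immune libraries interstitial macrophage markers summed to 2112 ± 79.3 CPM in HDM and 216 ± 24.7 in PBS. Glycolysis had 2 of 12 down and 10 not called (fry 0.0463; adjusted p = 0.47 with an estimated correlation), and the glycolysis and identity lists had the same counts adjusted over the list alone. Granule and activation genes had 5 up, 8 down and 3 not called of 16, also adjusted over the list alone, with a median log2 of −0.60, a mean of 0.14 and a fry direction of down (not called): S100a9 fell, at −0.88 ± 0.15, S100a8 at −0.76 ± 0.14 and Lcn2 at −1.36 ± 0.20. The growth factor Csf1 rose 1.92 ± 0.36 and the GTPase Rab15 6.39 ± 0.62. The gene count was 496 without HDM mouse 4, 492 without PBS mouse 1 and 401 without PBS mouse 2. Fry called 6 of 14 lists, 1 without HDM mouse 3, 2 without HDM mouse 4, and 0 without PBS mouse 1 or PBS mouse 2.

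In classical monocytes 49 of 4920 genes rose and 18 fell, and in non-classical ones 77 of 5943 rose and 55 fell (n = 4 and 4 mice each). The interferon-induced Slfn4 rose by a log2 fold change of 2.48 ± 0.26 in classical monocytes (adjusted p 0.000339), from 21.4 ± 8.12 to 122 ± 31.6 CPM, Usp18 by 1.67 ± 0.24 and Oasl2 by 1.24 ± 0.18, in an interferon list with 5 of 26 up and 21 not called (14 up adjusted over the list alone). In non-classical monocytes the matrix protein Thbs1 fell, at −1.95 ± 0.23 (0.000337), and Cd74 fell by 1.00 ± 0.13 (0.000758), from 1831 ± 379 to 916 ± 86.0 CPM, but with doublets kept Cd74 was at −0.13 and not called (0.744). MHC class II fell on balance there, with 4 of 10 down and 6 not called (7 down adjusted over the list alone; fry 0.0288; adjusted p = 0.044 with an estimated correlation). ER stress genes did too, with 2 of 16 down and 14 not called (8 down adjusted over the list alone; fry 0.0173; adjusted p = 0.045 with an estimated correlation). Cholesterol and fatty acid synthesis had 0 of 11 called (1 down adjusted over the list alone) and a median log2 of −0.35 (fry 0.0439; adjusted p = 0.1 with an estimated correlation). In classical monocytes fry called 0 of 15 lists (5 at 0.05 before adjustment), the mixed test 8 and camera 0. Their gene count was 11 without HDM mouse 1, 11 without HDM mouse 4, and 36, 25, 20 and 28 without PBS mouse 1, 2, 3 and 4, DESeq2 called 166, and fry called 1 list without PBS mouse 4. In non-classical monocytes the gene count was 60, 69 and 11 without HDM mouse 1, 2 and 4, and 59, 37 and 83 without PBS mouse 2, 3 and 4. Fry called 3 of 16 lists there, 0 without HDM mouse 2, HDM mouse 4 or PBS mouse 3, and 1 without HDM mouse 3, PBS mouse 2 or PBS mouse 4.

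Of 20 genes tied to allergic inflammation, 13 could be tested in the immune classes and 6 rose in 1 class each. Chil3 was tested in 9 classes, rose in alveolar macrophages and fell in B cells, CD4 and CD8 T cells, cDC2, neutrophils and NK cells, beside 1442 CPM in HDM and 5809 in PBS over whole libraries. Ccl6 rose in alveolar macrophages and fell in B cells, cDC2 and neutrophils, of 6 classes. Foxp3 rose in CD4 T cells, its only class, and the repair factor Areg was called there, 1 of 5 classes, at a log2 of 1.46 ± 0.33, from 110 ± 103 to 253 ± 58.8 CPM (adjusted p 0.0967 with DESeq2). Il1b rose in alveolar macrophages of 6 classes. Gata3 (3 classes), the mannose receptor Mrc1 (2), Ccl24 (1) and Il13 (1) were called in 0 classes. Il4, Il5, Arg1, Retnla and the antibody genes Ighg1, Ighe and Jchain could be tested in 0 classes at the planned cell minimum.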

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

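A closer look was taken at values of 1 sample far from the others of its group of 4 (Dixon's ratio of gap to range) and at responses that differed between 2 classes. Of the differences between classes, those of the macrophages were tested only after the cell counts were seen. Of 301 groups of 4 mice, 14 (4.65%) held such a sample, and chance gives about 1 in 20. Basophils or mast cells were 0% in HDM mouse 1 against 0.158 to 0.190% in the others, and 0.559% in PBS mouse 4 against 0.103 to 0.163%. Endothelial cells were 0.0784% in HDM mouse 1 and 0 in the others, and classical monocytes 8.16% in PBS mouse 1 against 5.77 to 5.93%. In B cells Cd74 was at 7382 CPM in PBS mouse 4 (others 6852 to 6926), Ssr4 at 155 in HDM mouse 2 (189 to 196) and Sdc1 at 6.77 in HDM mouse 4 (5.16 to 5.33). In CD4 T cells Il10 was at 29.6 CPM in PBS mouse 1 (0 to 4.51), Il13 at 66.7 and Calca at 0.902 in PBS mouse 3 (0 in the others), and Fabp5 at 274 in HDM mouse 4 (147 to 160). Chil3 was at 34.5 CPM in CD8 T cells of HDM mouse 2 (3.62 to 5.88), Tnfrsf18 at 24.9 in NK cells of PBS mouse 1 (52.2 to 57.0), and Saa3 at 26.5 in interstitial macrophages of PBS mouse 4 (0 to 1.73).

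By the test of the interaction, 57 genes differed between the responses of alveolar and adventitial fibroblasts: Acta2 by a log2 of 2.33, Csmd1 by 1.90, H2-Q7 by 3.86, Ifi203 by −2.30, Ifi211 by −1.85 and Col23a1 by −1.45 (adventitial minus alveolar). Between alveolar and interstitial macrophages 442 genes differed, with Ccl5 at 3.24, Siglec1 at 2.76, Rsad2 at −7.95, Cmpk2 at −6.46 and Mmp12 at −6.42 (interstitial minus alveolar).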

How the results depend on the processing

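Of the alternatives reported here, the minimum of 10 cells for interstitial macrophages and clustering without called genes were chosen only after the data were seen. Planned at 20 cells but not run was the interaction of macrophage class and treatment, and a mitochondrial limit of 5% left epithelial cells and cDC2 without enough cells to test. With 2 libraries per group, leaving out 1 leaves a lone sample, which edgeR, by pooling the spread, assumes to vary like the other group. Depth limits the small classes: epithelial cells had 22 cells in 1 library, and 2930 genes could be tested. The cause of the shifts below was not tested. Under all alternatives, 177 of 250 counts of genes and 117 of 164 counts of lists stayed within 1.5 times, 416 of 646 list calls were the same and 230 were lost, and 308 of 335 class shares were the same and 27 gained a call. Of the values of named genes, 3624 of 3677 were the same, 51 lost their call, 1 gained one, and Bgn in endothelial cells turned to 0.25 with doublets kept. Clustered without called genes, 27 of 27 class shares stayed uncalled.

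With the Wald test of DESeq2 the counts of changed genes were 286 (120 up and 166 down) in adventitial, 571 in alveolar and 819 in peribronchial fibroblasts, 4 in epithelial cells, 410 in immune cells of the mesenchymal libraries, 176 in pericytes, 83 in smooth muscle, 166 in classical monocytes, 457 in NK cells and 982 in interstitial macrophages. Without the expression filter they were 1149 in adventitial fibroblasts, 404 in endothelial, 53 in epithelial and 1345 in immune cells of the mesenchymal libraries, 247 in classical and 248 in non-classical monocytes, 1256 in interstitial macrophages, and 207 and 750 for the fibroblast and macrophage interactions. Keeping doublets gave 80 in endothelial cells, 332 in pericytes, 821 in CD8 T cells and 18 in classical monocytes, a mitochondrial limit of 5% 2 in endothelial cells and 809 in CD8 T cells, and Leiden resolution 2 844 in CD8 T cells. DESeq2 size factors gave 1 list in adventitial fibroblasts and 8 in interstitial macrophages. Camera with an estimated correlation called 0 lists in adventitial and peribronchial fibroblasts, epithelial cells, B cells, CD4 T cells, cDC2, neutrophils and interstitial macrophages, 1 in alveolar macrophages and 3 in NK cells. edgeR on cell counts called 4 mesenchymal and 10 immune shares.

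The labels number the samples of each group alike, but samples of the same number were not alike (correlations −0.0226 in the mesenchymal libraries, 0.0109, 0.0858, −0.107 and −0.106 in the immune mice). With the replicate block, changed genes were 206 in endothelial, 37 in epithelial and 384 in immune cells of the mesenchymal libraries, 378 in smooth muscle, 1046 in cDC2, 10 in classical and 39 in non-classical monocytes, 429 in neutrophils and 324 in interstitial macrophages. Lists called were 0 in adventitial and peribronchial fibroblasts, epithelial cells, CD8 T cells, cDC2, neutrophils and non-classical monocytes, 2 in pericytes and 1 in interstitial macrophages, and class shares called were 3 mesenchymal (1 up, 2 down) and 10 immune.

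Leaving out each library in turn gave 748 to 1459 changed genes in alveolar fibroblasts, 52 to 368 in endothelial, 17 to 85 in epithelial and 467 to 808 in immune cells of the mesenchymal libraries, 0 to 797 in pericytes, 143 to 360 in smooth muscle, 1031 to 1793 in cDC2, 11 to 65 in classical and 11 to 118 in non-classical monocytes, 401 to 799 in neutrophils, 343 to 1074 in interstitial macrophages, and 28 to 129 and 285 to 511 for the fibroblast and macrophage interactions. Lists ranged from 0 to 2 in adventitial, alveolar and peribronchial fibroblasts, 0 to 0 in epithelial cells, 1 to 2 in CD8 T cells, 0 to 1 in classical and 0 to 4 in non-classical monocytes, 0 to 5 in neutrophils and 1 to 6 in interstitial macrophages.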

Other observations

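Several small immune classes were too few for tests of genes. Type 2 innate lymphoid cells were 0.352 ± 0.195% of kept cells in HDM and 0.611 ± 0.231% in PBS (exact permutation p 0.171, n = 4 and 4 mice), cDC1 1.02 ± 0.203% and 1.39 ± 0.619% (0.343), plasmacytoid dendritic cells 0.769 ± 0.249% and 0.873 ± 0.461% (0.657) and basophils or mast cells 0.130 ± 0.0876% and 0.247 ± 0.210% (0.514), and 0 of these 4 classes were called by edgeR. No eosinophil cluster formed: the peroxidase Epx had 0 counts in immune mice and Prg2 0.156 (HDM) and 0.0335 CPM (PBS). Other genes made the marker sum, 17.4 ± 1.84 and 62.3 ± 11.1. The secretoglobin Scgb1a1 of airway club cells was at 53.3 and 551 CPM in the mesenchymal HDM libraries and 4.24 and 10.8 in PBS. Xist was expressed in all 12 samples, at 740 to 1765 CPM.

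Of the tests below, those of a shift of the whole HDM capture, of RNA released by alveolar macrophages and of the immune capture wells, and the macrophage interaction, were chosen only after the result was seen. The ribosomal protein share was higher in HDM in B cells (26.1 and 17.9%), NK cells (16.9 and 11.8%), CD8 T cells (33.7 and 28.4%) and classical (17.1 and 15.5%) and non-classical monocytes (13.7 and 11.3%), and was at 9.77 and 9.20% in alveolar macrophages and 20.8 and 23.2% in CD4 T cells. Fewer UMI per cell are argued against by B cells' medians, 4223 (HDM) and 4256 (PBS). In 1396 UMI-matched cells the log2 ratio was 0.48 ± 0.0647 (0.55 in all B cells). A shift of the whole HDM capture that acts on every cell alike is argued against by the log2 ratio within the clusters with most PBS cells, 0.51 in NK, 0.37 in B, 0.35 in CD4 T, 0.28 in non-classical monocytes, 0.25 in CD8 T and 0.15 in classical monocytes (range 0.37 ± 0.0799, exact permutation p 0.0286, the smallest possible), and 0.07 in alveolar macrophages, left out of the test for as few as 3 cells. A treatment effect within the Ighd-led B-cell cluster remains a candidate explanation (0.37 ± 0.0388, 1475 cells). A change of subsets as a part and a capture effect that differs by class stay open.

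Chil3 and Lyz2 were lower in lymphocytes of HDM mice. Expression by the lymphocytes themselves is argued against by levels of Chil3, without TMM scaling, that were much alike in the 4 lymphocyte classes of PBS mice, 54.2 CPM in B, 54.8 in NK, 42.4 in CD4 T and 52.0 in CD8 T cells, highest over lowest 1.29. RNA released by alveolar macrophages, which were fewer in HDM mice, may account for the change: over 7 macrophage transcripts the log2 change in lymphocytes differed from that in the whole library by a median of −0.29 (spread 0.595). Of 20 pairs of transcript and class 19 were lower in HDM, with Mt1 in CD4 T cells the exception. Mctp1 in B and NK cells moved less than the library, by −0.59 and −0.03.

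The interferon response list had a median change above 0 in 8 of 8 mesenchymal classes (fry called 2). Free RNA from 1 interferon-responding cell type stays open. Over 8 classes the list's 19 genes had median ranges of 2.44 and 2.49 log2 in the HDM libraries (1 source: under 0.608). These are levels, not changes from PBS. That 7 of 8 classes passed the mixed test restates the pattern and decides nothing about the capture wells of the immune libraries. A handling batch shared by the HDM libraries of a compartment cannot be told apart from treatment. As far as the tags tell, 0 captures hold both groups, and tags of the other 3 mice of an immune group gave 71.9 to 197 UMI per cell.

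The 8 immune mice can be split in 35 ways into groups of 4 (or 4 and 3 where a mouse is missing). For changed genes chance can be excluded in all 10 immune classes and the macrophage interaction, where 1 of 35 splits, the real one, gave as many. The real counts and the highest of the other splits were 2172 and 1 in alveolar macrophages, 2679 and 1 in B cells, 3561 and 0 in CD4 T cells, 338 and 9 in CD8 T cells, 1615 and 2 in cDC2, 67 and 7 in classical monocytes, 784 and 16 in neutrophils, 751 and 12 in NK cells, 132 and 7 in non-classical monocytes, 610 and 0 in interstitial macrophages, and 442 and 16 for the interaction. For lists called chance is argued against, again with 1 of 35, in alveolar macrophages (7 and 1), B cells (8 and 0), CD4 T cells (12 and 2) and cDC2 (3 and 1). The same held in neutrophils (6 and 1), NK cells (8 and 1), non-classical monocytes (3 and 1) and interstitial macrophages (4 and 0). It did not hold in CD8 T cells (1 and 1, 4 of 35 splits). In classical monocytes the real count was 0 (highest other 3), which all 35 of 35 splits reach, so nothing is decided.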
